A study of Oryza sativa with 4 samples.

How the data were processed

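Gene expression was measured in seedlings of the rice cultivar Zhonghua 11 on 4 dual-colour oligonucleotide arrays (Agilent rice design). Per the labels, the seedlings were grown at 26 °C on Murashige and Skoog medium. One channel of every array held RNA of seedlings heat-shocked for 6 h and the other held RNA of untreated seedlings of the same age. The temperature of the heat shock is not given in the sources used here. There were 2 arrays of 24-day and 2 of 18-day seedlings, and per the labels the dyes were exchanged between the arrays of an age, with heat-shocked RNA in Cy5 on replicate 1 and in Cy3 on replicate 2. The series' design text calls the samples biologically independent, while the sample titles could also be read as a dye exchange of one RNA pair. The p-values may therefore measure only technical spread.

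Per the file headers, the slides were scanned and the spots measured with Agilent Feature Extraction 10.5.1.1 and the protocol GE2_105_Dec08. The intensity columns used here are, per the file headers, each spot's mean pixel brightness and the median brightness of its local background, in both dyes and before normalization. The same files hold the scanner software's processed signals, intensity values that per the file headers were background-subtracted, detrended and dye-normalized within the array. They also hold a log10 ratio of the processed Cy5 over Cy3 signal, per the file headers. The deposited series matrix holds log2 values whose processing its text does not state. Set against the scanner files' ratios, its columns equalled the log2 ratio of heat-shocked over untreated signal within 0.001 for 91.8% to 94.1% of the probes, with medians of 0.07, -0.04, 0.01 and -0.10 for 24-day replicates 1 and 2 and 18-day replicates 1 and 2. This settles their direction and scale, and what was done to the other probes remains unknown.

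Each array held 45151 spots, of which 43254 were not controls, for 42429 probes. The share of these spots well above background was 82.4% to 87.0% per channel, between 82 and 182 spots per array were outliers, and 0 were saturated. The number of arrays limits the precision. Mean signals were corrected with normexp and an offset of 50, fitted on all spots, and normalized by loess within each array with control spots at weight 0 (limma 3.58.1, statmod 1.5.0, R 4.3.3). Control and outlier spots were left out, spots of one probe were averaged, and probes were kept where both arrays of at least 1 of the 4 RNAs (age by treatment) were well above background. Of a gene's probes the one with the highest mean brightness was used, which left 25664 features, called genes here. Of 7056 genes with several probes, the probes were called in opposite directions for 146 at 24 days and 58 at 18 days. Gene names are the array files' descriptions, which can be old, because 0 of the locus identifiers and 0 of the accessions matched the reference table. Coordinates are therefore not printed, and the genome build is not given in the sources used here.

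The log2 ratios of heat-shocked over untreated signal were fitted over all 4 arrays with limma's lmFit and eBayes, with 1 coefficient per age and 2 residual degrees of freedom, so that both ages share one estimate of the spread. A dye effect that adds to the log2 ratio cancels in each age's mean but stays in the spread. The median residual SD between arrays was 0.188, and 0.0761 with a dye term. Spots of 1 probe on an array had a median SD of 0.0667, over 35 probes with 10 spots. Limma called a dye effect for 0 genes, with 7450 at an unadjusted p under 0.05. The SEs and p-values of the main fit therefore hold dye bias as well as other spread. The difference between the ages was the contrast of the 24-day minus the 18-day coefficient. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes are limma's. The untreated seedlings of both ages were never hybridised together. They were compared by limma's separate-channel fit on Aquantile-normalized channels, with a correlation within spots of -0.338. Where a gene was not well above background in one RNA on both arrays, the fold is given as "at least", the mean of the brighter RNA against the mean of, per array, the higher of the dim probe's own value and the lowest signal among probes well above background.

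There were 38 gene lists, defined by words in the array descriptions, and 37 of them had the 3 or more tested genes that a test needed. They were small heat shock proteins, HSP70 chaperones, DnaJ co-chaperones, HSP90 with HSP100 and chaperonins, heat stress transcription factors, ER folding, programmed cell death, autophagy, antioxidant enzymes, glutathione S-transferases, class III peroxidases, photosystem and antenna proteins, Calvin cycle, chlorophyll biosynthesis, core histones and replication, cyclins and cell cycle kinases, cytosolic ribosomal proteins, organelle ribosomal proteins, proteasome, defence proteins, WRKY, NAC, and ERF with DREB factors, ethylene and jasmonate synthesis, jasmonate ZIM proteins, auxin response, LEA and dehydrins, galactinol with raffinose and trehalose, cell wall loosening and synthesis, aquaporins, alternative respiration, chlorophyll breakdown and senescence, splicing factors, seed storage, root and meristem markers, reference genes, and the transgene family with 1 gene. Lists were tested in both directions with camera at a preset correlation between genes of 0.01, adjusted over the 37 lists, with an estimated correlation and with fry as alternatives. Camera asks whether a list changed more than the other genes, and fry whether its own members changed at all. A call gained or lost in fry therefore answers another question. A gene can stand in several lists.

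The groups, tests, lists, rule for named genes and alternatives were fixed before the data were examined, except that counting identical probe sequences once and a replicate block were added afterwards, as were the tests of explanations named as such in the closing section, and the families, transposable elements and clock genes with their tests. The rule named the transgene family, the 8 largest rises and 8 largest falls at each age, the 6 largest differences in each direction between the ages and between the untreated seedlings, and up to 4 genes of each list. The largest rises and falls had an informative description and the same direction on both arrays. The largest differences had an informative description and single-array values that did not overlap between the ages. Each of these rankings took at most 2 genes from any list. The up to 4 genes of a list only had to be called at either age, and the transgene family had no condition. The alternatives were no background correction, the scanner's processed signals, an offset of 10, median centring in place of loess, Aquantile between arrays, no filter and a stricter filter on dim probes, a dye term with 1 residual degree of freedom, every probe on its own, a change of at least 2-fold, the series matrix's values, an intensity trend with robust variances, the arrays of an age as 1 replicate, and each array left out in turn. For the untreated comparison they were no filter, quantile normalization over all channels, no background correction and each array left out, where the fit kept the within-spot correlation of all 4 arrays.

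The fits were tested on simulated data with 200 of 25664 genes changed. Of 66 genes changed by 2 on the log2 scale, 33 were recovered in the 24-day fit, 22 in the 18-day fit and 0 in the fit of the difference. In each of these fits, 0 of 67 genes changed by 1 and 0 of 67 changed by 0.5 were recovered. The median estimates of the changes of 2 were 2.00, 1.99 and 2.01. With 12832 genes changed by 1, 89.6% were recovered in the 24-day fit and 2.72% of the calls were false. The difference was simulated only with 200 genes changed. In the data it was called for 1299 genes, so its 0 recoveries do not give the smallest difference that the fit can detect. The separate-channel fit, run on 5000 genes with 200 changed, recovered 59 of 66 changes of 2, 40 of 67 changes of 1 and 20 of 67 changes of 0.5. It made 8 false calls. Its simulated channels shared a spot term, which gives a positive correlation within spots, whereas that of the data was -0.338. A larger share of its genes was changed, so its counts cannot be set against those of the other fits. Of 100 random lists of 30 genes, camera gave 1 an unadjusted p under 0.05. Each simulated gene was drawn independently, so this does not show how camera behaves for lists of correlated genes. Heat-shocked seedlings without the transgene were not analysed here.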

Results

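The 4 arrays compared RNA of heat-shocked and untreated transgenic rice seedlings of a study of OsPDCD5, a gene related to programmed cell death, by inducible expression. Per the series' design text, the 24-day seedlings were sampled before signs of cell death appeared, to find genes involved in the death that OsPDCD5 induces. The 18-day seedlings were included to ask why expression of the same gene did not induce death in them. Each age had 2 arrays with the dyes exchanged, and the median spot signal per channel lay between 1061 and 2876 over median backgrounds of 20 to 98.5. All seedlings analysed here carried the transgene, so a response to heat and a response to OsPDCD5 cannot be separated in any comparison of heat-shocked with untreated seedlings.

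The probe of the OsPDCD5 family rose modestly at both ages. The only tested gene described as a TFAR19-related protein was Os05g0546500, and TFAR19 is another name of PDCD5. Its signal was 1.51-fold higher after heat shock in 24-day seedlings, a log2 change of 0.60 (SE 0.11, n = 2 arrays, limma adjusted p = 0.00911) with 0.58 and 0.62 on the single arrays. In 18-day seedlings it was 1.35-fold higher, a log2 change of 0.43 (SE 0.11, n = 2 arrays, limma adjusted p = 0.0321) with 0.38 and 0.49 on the single arrays. The changes at the ages did not differ by the test of the difference, 0.17 (SE 0.15, limma adjusted p = 0.580), and the untreated seedlings of the ages differed by -0.18 (limma adjusted p = 0.201). With median centring in place of loess the 18-day change was -0.04 (adjusted p = 0.930) and the 24-day change was 0.58 (adjusted p = 0.152). Both calls also ended without 24-day replicate 1 or 2, and the 18-day call without 18-day replicate 2. Over all alternatives the adjusted p ran from 0.010 to 0.930 at 18 days and from 0.000640 to 0.152 at 24 days. Whether the probe lies within the transferred construct is not known from the sources used here, so it may read the native gene, the transgene or both.

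In 24-day seedlings, 6 h of heat shock raised heat shock proteins and heat stress transcription factors, and lowered cell wall, cell cycle, auxin and peroxidase genes. The calls of these lists by camera at a preset correlation all ended with an estimated correlation, which weakened even the planted list of the simulation. For HSP90, HSP100 and chaperonins the unadjusted camera p went from 1.02e-06 to 0.0296. Their estimated correlation, -0.00474, was below the preset 0.01. Those of the other lists named here were above it, from 0.0128 for small heat shock proteins to 0.0608 for heat stress transcription factors. Over all lists that passed at either age the estimates ran from -0.0217 for seed storage markers to 0.273 for ER folding. Where the estimate is above 0.01, camera's p-values at the preset correlation may be too small. The 17 kDa heat shock protein Os01g0135800 rose 406-fold (log2 8.67, SE 0.26, n = 2 arrays, limma adjusted p = 0.000228). A calmodulin-binding IQ domain protein, Os11g0506800, rose 588-fold (log2 9.20, SE 0.45, with 10.10 and 8.31 on the single arrays), and the alpha-amylase Os08g0473900, a starch-degrading enzyme, rose 407-fold (log2 8.67, SE 0.16). The deepest falls included the leucine-rich repeat protein Os02g0616100 at -5.82 (SE 0.30, with -5.22 and -6.43 on the single arrays) and the fasciclin-domain protein Os02g0308800 at -5.58 (SE 0.12). Of 25664 genes, 13844 (53.9%) were called, 6476 higher and 7368 lower, and 2575 rose and 3391 fell at least 2-fold. With median centring the share of higher calls was 32.9% in place of 46.8%, and 7762 genes were called. Without 24-day replicate 1 the calls numbered 7611, and without 24-day replicate 2 they numbered 7337.

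Most small heat shock proteins, HSP70 and HSP90 chaperones rose at 24 days. Of 28 small heat shock proteins, which hold unfolding proteins in solution, 16 rose, 4 fell and 8 did not pass, with 17 rising and 4 falling when adjusted over the list alone. Os01g0136200 changed by 8.17 (SE 0.90) and the class IV protein Os04g0445100 by 8.14 (SE 0.87). These values depended on the dye orientation, with 9.80 and 6.55 and with 9.57 and 6.71 on the single arrays. Their untreated log2 signals were lower in Cy3 than in Cy5 at both ages, while the heat-shocked signals moved less. For Os01g0136200 these were 9.05 against 12.30 at 24 days and 10.07 against 12.46 at 18 days. For Os04g0445100 they were 9.36 against 11.76 and 9.68 against 12.17. The means therefore average over 2 unlike values. Among 18 HSP70 chaperones 13 rose and 1 fell, the same counts as adjusted over the list alone, led by Os03g0277300 at 6.50 (SE 0.28) and Os05g0460000 at 5.29 (SE 0.16). Of 36 HSP90, HSP100 and chaperonin genes 25 rose, 1 fell and 10 did not pass (25 and 3 adjusted over the list alone), among them HSP81-1 Os04g0107900 at 7.83 (SE 0.94, with 9.49 and 6.18 on the single arrays), HSP82 Os09g0482600 at 5.13 and ClpB Os03g0426900 at 4.54 (with 5.18 and 3.91 on the single arrays). Of 22 heat stress transcription factors 14 rose and 5 fell (15 and 5 adjusted over the list alone), with 6.09 for Os03g0745000 (6.77 and 5.42 on the single arrays) and 5.48 for RHSF2 Os08g0546800. Against all other genes, camera gave adjusted p-values of 0.00149 for small heat shock proteins, 0.000493 for HSP70, 1.26e-05 for HSP90 with HSP100 and 0.00408 for the transcription factors. With an estimated correlation these were adjusted p = 0.270, 0.270, 0.270 and 0.329, the highest over the alternatives. Of 82 DnaJ co-chaperones 23 rose and 14 fell (21 and 12 adjusted over the list alone) and the list did not pass (adjusted p = 0.154), although Os01g0606900 rose 388-fold and Os05g0562300 rose 50.6-fold (log2 5.66, with 6.49 and 4.83 on the single arrays). Of 14 ER folding genes 8 rose and 1 fell, also when adjusted over the list alone (list adjusted p = 0.128). The luminal binding proteins Os03g0710500 and Os05g0367800 rose by 4.10 and 3.57, and the protein disulfide-isomerase Os05g0156300 fell by 1.53. The defining words also place luminal binding proteins in the HSP70 list and endoplasmin in the HSP90 list, so results of these lists are not independent of ER folding.

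Genes annotated to programmed cell death moved in both directions at 24 days. Of 29 such genes 6 rose, 10 fell and 13 did not pass, with the same 6 and 10 adjusted over the list alone. The cell death suppressor Bax inhibitor-1 (Os02g0125300) rose by 1.92 (SE 0.16). The BAG-domain genes Os09g0524800 and Os06g0126500 fell by 2.66 (SE 0.16) and 2.30 (SE 0.26), and the vacuolar processing enzyme Os01g0559600, a protease, fell by 1.79 (SE 0.11). The list did not pass (camera adjusted p = 0.691), and its median of 0.01 differed in sign from its mean of -0.22 and from the direction of the test. Of 10 autophagy genes 1 fell and 9 did not pass, also when adjusted over the list alone. That gene was Autophagy 4a, Os04g0682000, at -0.60 (SE 0.11, list adjusted p = 0.976).

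More antioxidant genes rose than fell, while most class III peroxidases fell. Of 44 antioxidant enzymes 24 rose, 5 fell and 15 did not pass, with the same counts of 24 and 5 adjusted over the list alone. The dehydroascorbate reductase Os05g0116100 changed by 1.76 (SE 0.13), the peroxiredoxin Os07g0638400 by 1.57 (SE 0.10) and the superoxide dismutase Os07g0665200 by 1.12 (SE 0.10), while the nectarin Os01g0249200 fell by 2.40 (SE 0.28). Of 81 class III peroxidases, enzymes that act mostly in the cell wall, 15 rose and 48 fell (18 and 49 adjusted over the list alone). Os05g0499300 changed by -4.70 and Os03g0339300, a peroxidase outside the list, by -5.01, while Os10g0106900 was at least 25.4-fold higher, its untreated signal being not well above background. Camera gave adjusted p = 0.00525 for antioxidant enzymes and 0.000189 for class III peroxidases, and for both adjusted p = 0.270 with an estimated correlation. Of 61 glutathione S-transferases 24 rose and 12 fell (25 and 12 adjusted over the list alone), with 3.69 for Os01g0558100 and -2.67 for Os10g0543800, and the list did not pass (adjusted p = 0.0707). Of 13 alternative respiration genes 5 rose and 4 fell (6 and 4 adjusted over the list alone, list adjusted p = 0.184), led by the alternative oxidase Os04g0600300 at 3.88 (SE 0.12).

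Of the cell wall and cell cycle lists most genes fell at 24 days, as did more histone and auxin response genes than rose, and these list calls ended with an estimated correlation. Of 106 genes for cell wall loosening and synthesis 8 rose, 70 fell and 28 did not pass (11 and 73 adjusted over the list alone), among them the expansins Os01g0823100 at -4.03 (SE 0.11) and Os02g0658800 at -3.50 (SE 0.18) and the pectinesterase-like Os07g0119400 at -3.34 (SE 0.12). Of 46 cyclins and cell cycle kinases 1 rose and 31 fell, also when adjusted over the list alone, including the B-like cyclin Os06g0726800 at -2.23 and the kinesin Os03g0587200 at -2.11. Of 53 core histone and replication genes 7 rose and 28 fell (7 and 30 adjusted over the list alone). Histone H2A Os05g0113900 and histone H3 Os04g0419600 changed by -3.23 and -2.96, while histone H2B.2 Os05g0460500 rose by 4.21 (SE 0.42, with 4.95 and 3.48 on the single arrays). Of 69 auxin response genes 6 rose and 36 fell (6 and 39 adjusted over the list alone), with -2.86 for the AUX/IAA gene Os03g0797800 and 2.08 for the SAUR gene Os10g0510500. Camera gave adjusted p-values of 4.09e-07 for cell wall, 1.30e-05 for cyclins, 0.00513 for histones and 0.00132 for auxin response, and all 4 had adjusted p = 0.270 with an estimated correlation. Of the lists meant as markers of tissues, the meristem and seed storage lists passed downward at the preset correlation and the root list did not pass. They were defined by words in the descriptions, so their members need not be particular to those tissues. Of 16 meristem markers 0 rose and 6 fell by limma (0 and 7 at an unadjusted p under 0.05), 5 of them adjusted over the list alone, including Growth-regulating factor 3 Os04g0600900 at -1.80 (list adjusted p = 0.0227, adjusted p = 0.420 with an estimated correlation and 0.0828 without 24-day replicate 1). Of 40 seed storage markers 6 rose and 23 fell (8 and 25 adjusted over the list alone), among them the lipid transfer protein Os04g0554800 at -4.19. The seed list had adjusted p = 0.00253, against adjusted p = 0.270 with an estimated correlation and 0.0723 with no filter on dim probes. Of 35 root markers 9 rose and 14 fell, also when adjusted over the list alone (list adjusted p = 0.360), with -3.06 for RCc2 Os10g0552300.

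Most splicing factors rose, most cytosolic ribosomal proteins did not pass, and photosynthesis genes as a group did not pass. Of 32 splicing factors 18 rose and 0 fell by limma (19 and 0 adjusted over the list alone, 21 and 0 at an unadjusted p under 0.05), with 74.5-fold for PRP18 Os03g0701100 (log2 6.22, SE 0.14) and 9.73-fold for the PHD finger-like protein Os05g0367000. Of 156 cytosolic ribosomal proteins 31 rose, 7 fell and 118 did not pass (23 and 3 adjusted over the list alone), led by acidic protein P3 Os01g0231700 at 1.61 (SE 0.10). Of 47 organelle ribosomal proteins 17 rose and 3 fell (16 and 3 adjusted over the list alone), including the plastid protein Os03g0856500 at 1.59 (SE 0.36). Camera's adjusted p was 0.000189 for splicing, 0.0101 for cytosolic and 0.00718 for organelle ribosomal proteins, against adjusted p = 0.270, 0.633 and 0.270 with an estimated correlation. The cytosolic list also lost its call in fry (adjusted p = 0.122) and without 24-day replicate 2 (adjusted p = 0.155), and the organelle list without 24-day replicate 2 (adjusted p = 0.0538). Of 57 proteasome genes 10 rose and 1 fell (3 and 0 adjusted over the list alone), with 1.58 for the maturation factor Os02g0800100 (list adjusted p = 0.128). Of 43 photosystem and antenna genes 5 rose and 5 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.778), and the direction of the list turned upward with median centring (adjusted p = 0.324). Without 24-day replicate 1 the list passed downward (adjusted p = 0.0301) and without 24-day replicate 2 it turned upward (adjusted p = 0.104), so the single arrays disagreed, and over all 9 alternatives the adjusted p ran from 0.0301 to 0.986. Their largest rises included the Q(B) protein Os04g0235200 at 2.04 and the oxygen-evolving protein Os02g0578400 at 1.11. Of 28 Calvin cycle genes 7 rose and 6 fell, also when adjusted over the list alone (list adjusted p = 0.992), with -0.69 for the Rubisco large chain Os10g0356000 and 1.05 for the Rubisco-binding chaperonin Os12g0277500. Of 14 chlorophyll biosynthesis genes 1 rose and 6 fell (0 and 5 adjusted over the list alone, list adjusted p = 0.216), with -2.22 for the protochlorophyllide reductase Os04g0678700. Of 13 chlorophyll breakdown and senescence genes 2 rose and 6 fell, also when adjusted over the list alone, with 1.89 for Os03g0241900 and -2.24 for Os06g0262800. That list did not pass (adjusted p = 0.563), and its median of 0.08 differed in sign from its mean of -0.24.

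LEA proteins and dehydrins, which protect cells during drying, rose at 24 days, and more WRKY and NAC transcription factors fell than rose. These list calls ended with an estimated correlation. Of 26 LEA and dehydrin genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with 4.29 for Os06g0110200, 3.43 for COR410 Os02g0669100 and 3.07 for RAB 16B Os11g0454200. Of 66 WRKY factors 9 rose and 28 fell, also when adjusted over the list alone, including Os01g0821600 at -3.90 and WRKY 69 Os08g0386200 at -3.02. Of 57 NAC factors 3 rose and 25 fell (3 and 24 adjusted over the list alone), with -3.63 for Os04g0460600 and -0.90 for Os07g0683200. Camera gave adjusted p-values of 1.26e-05 for LEA, 0.0264 for WRKY and 0.0433 for NAC, against adjusted p = 0.270, 0.340 and 0.270 with an estimated correlation. The NAC list also lost its call with no filter on dim probes (0.0723), with median centring (0.0582) and without 24-day replicate 2 (0.0570). Of 86 ERF and DREB factors 22 rose and 32 fell (24 and 34 adjusted over the list alone), with a median of -0.11, a mean of 0.05 and adjusted p = 0.693. The AP2-domain gene Os02g0546600 rose 99.7-fold (log2 7.29 and 5.98 on the single arrays), the coactivator Os06g0592500 78.2-fold (log2 7.78 and 4.80 on the single arrays) and RAP2.6 Os12g0168100 24.1-fold. Of 171 defence proteins 39 rose and 76 fell (41 and 78 adjusted over the list alone, list adjusted p = 0.104). The trypsin inhibitor Os01g0124000 rose by 4.21 and PR1 Os07g0129300 fell by 3.04. The chitinase Os01g0860500 changed by 4.85, but by 0.29 (adjusted p = 0.0770) on another of its probes. Of 35 ethylene and jasmonate synthesis genes 3 rose and 9 fell, also when adjusted over the list alone (list adjusted p = 0.154), with 3.95 for the oxophytodienoate reductase Os06g0216300 and -1.92 for allene oxide synthase Os03g0767000. Of 13 jasmonate ZIM genes 2 rose and 7 fell, also when adjusted over the list alone (list adjusted p = 0.0613), with -2.32 for Os03g0180800. Of 14 galactinol, raffinose and trehalose genes 5 rose and 5 fell, also when adjusted over the list alone (list adjusted p = 0.853), among them a raffinose synthase Os07g0209100 at 3.45 and a trehalose-phosphate phosphatase Os02g0661100 at -2.86. Of 13 aquaporins 2 rose and 4 fell, also when adjusted over the list alone (list adjusted p = 0.691), with 1.08 for PIP2.3 Os09g0541000. The aquaporin Os06g0228200 changed by -1.95, but by -0.17 (adjusted p = 0.297) on another of its probes. Of 18 reference genes 3 rose and 7 fell, also when adjusted over the list alone (list adjusted p = 0.445), and actin 7 Os12g0163700 and actin 1 Os03g0718100 fell by 1.52 and 1.13. Other deep falls were those of the proline-rich protein Os04g0644400 at -5.66, the CER1-like gene Os02g0814200 at -5.51, the rhomboid-like gene Os10g0521900 at -5.22 and the cytochrome P450 Os03g0658800 at -5.70. The P450 changed by -0.39 (adjusted p = 0.0764) on another of its probes, and Os02g0230300, described as protodermal factor 1, was at least 32.0-fold lower, being not well above background after heat shock. For the P450, the chitinase Os01g0860500 and the aquaporin Os06g0228200 the other probe's adjusted p was the highest over the alternatives. Without 24-day replicate 1 the 24-day calls of Os04g0682000, Os10g0356000, Os03g0856500 and Os12g0548700 ended, without 24-day replicate 2 those of Os04g0682000, Os07g0683200 and Os09g0541000, and with median centring those of Os04g0682000 and Os10g0356000.

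**Figure D1:**
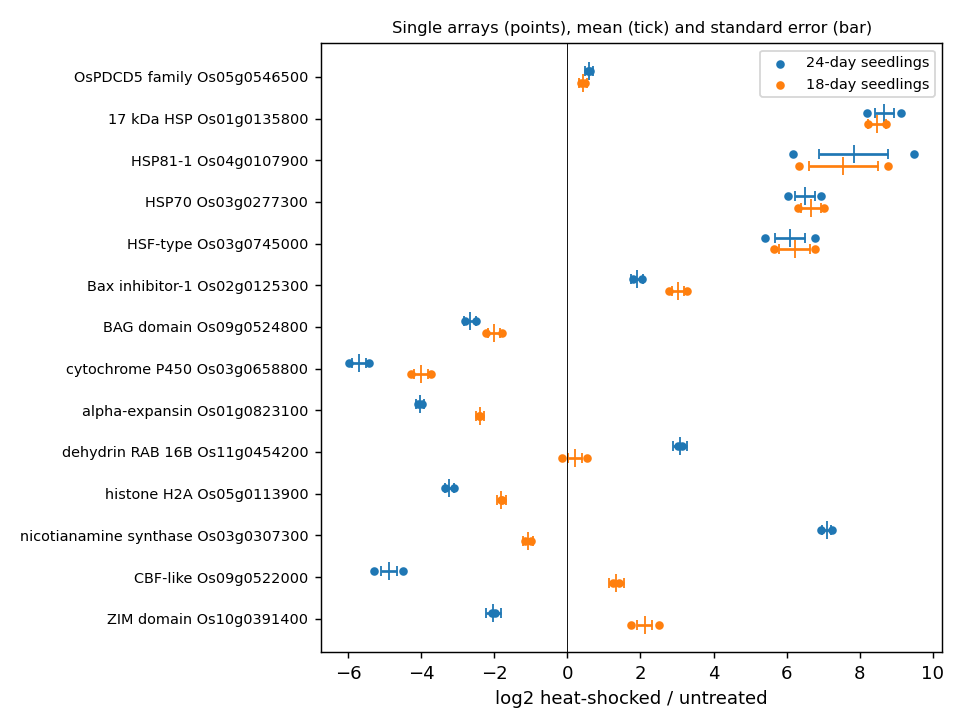
Log2 ratio of heat-shocked over untreated signal (horizontal axis) of 14 named genes (vertical axis) in 24-day and 18-day seedlings, with single arrays as points, the mean of 2 arrays as a tick and the limma standard error as a bar. The 17 kDa heat shock protein lies at 8.67 and 8.47, whereas the nicotianamine synthase lies at 7.10 in 24-day and -1.07 in 18-day seedlings.

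In 18-day seedlings, heat shock raised small heat shock proteins, HSP70 and HSP90 chaperones, and more cell wall, auxin and class III peroxidase genes fell than rose. The calls of these lists ended with an estimated correlation. The 17 kDa heat shock protein Os01g0135800 rose 355-fold (log2 8.47, SE 0.26, n = 2 arrays, limma adjusted p = 0.000418) and the IQ domain gene Os11g0506800 rose 477-fold (log2 8.90, SE 0.45). The class I small heat shock protein Os01g0136000 changed by 7.83 (SE 0.88, with 8.99 and 6.66 on the single arrays) and heat shock protein 26 Os03g0245800 by 7.69 (SE 1.15, with 9.38 and 6.01). Their untreated log2 signals at 18 days were 9.77 and 9.90 in Cy3, against 12.12 and 13.46 in Cy5. Of 25664 genes, 9998 (39.0%) were called, 4822 higher and 5176 lower, and 2124 rose and 1997 fell at least 2-fold. With a dye term 15371 genes were called, and with the arrays of an age as 1 replicate and no test 2930 changed at least 2-fold on both. Across genes, which are not independent replicates, the changes at the ages correlated with r = 0.858 (Spearman 0.817). Genes called higher at both ages numbered 3876, against 1217 for independent lists, and those called lower at both numbered 4195, against 1486. Both ages share one estimate of each gene's spread, so their calls are not independent and the excess over these counts is partly built in.

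Of 28 small heat shock proteins 16 rose and 3 fell at 18 days (18 and 3 adjusted over the list alone). Of 18 HSP70 chaperones 11 rose and 1 fell (12 and 2 adjusted over the list alone), led by Os03g0277300 at 6.67 (SE 0.28), and of 36 HSP90, HSP100 and chaperonin genes 20 rose and 1 fell (23 and 1 adjusted over the list alone), led by Os04g0107900 at 7.55 (SE 0.94, with 8.76 and 6.35 on the single arrays). Of 22 heat stress transcription factors 10 rose and 3 fell (11 and 3 adjusted over the list alone), with 6.22 for Os03g0745000, 5.19 for Os01g0733200 and 5.07 for Os02g0527300. Of 14 ER folding genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with luminal binding proteins again counted in the HSP70 list too. Camera's adjusted p was 0.00114 for small heat shock proteins, 0.000225 for HSP70, 8.45e-06 for HSP90 with HSP100, 0.0305 for the transcription factors and 0.00336 for ER folding. With an estimated correlation these were adjusted p = 0.332, 0.332, 0.332, 0.429 and 0.462. With median centring the transcription factors (adjusted p = 0.0694) and ER folding (adjusted p = 0.0959) lost their calls, and a dye term also ended that of the transcription factors (adjusted p = 0.107). Of 29 programmed cell death genes 6 rose and 8 fell (8 and 11 adjusted over the list alone, list adjusted p = 0.449). Bax inhibitor-1 Os02g0125300 rose by 3.02 (SE 0.16) and the BAG-domain genes Os09g0524800 and Os06g0126500 fell by 2.00 and 1.97. Of 10 autophagy genes 0 rose and 2 fell by limma, 0 of them adjusted over the list alone, against 1 and 2 at an unadjusted p under 0.05 (list adjusted p = 0.858), and these were Os01g0681400 at -0.40 and Os04g0682000 at -0.37, whose calls ended with a normexp offset of 10 and without 18-day replicate 2.

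Of 106 cell wall genes 6 rose and 47 fell (6 and 49 adjusted over the list alone), with -2.40 for the expansin Os01g0823100. Of 69 auxin response genes 3 rose and 31 fell (6 and 34 adjusted over the list alone), with -2.56 for Os03g0797800 (-1.90 and -3.22 on the single arrays). Of 81 class III peroxidases 6 rose and 35 fell, also when adjusted over the list alone, with -3.57 for Os05g0499300 and 2.74 and 4.95 on the single arrays for Os10g0106900. The untreated log2 signals of Os10g0106900 were 7.03 and 6.54, near the 6.60 and 6.81 of 24 days, which were not well above background. Of 171 defence proteins 26 rose and 68 fell (29 and 72 adjusted over the list alone), and PR1 Os07g0129300 changed by -4.35 (SE 0.20). Of 66 WRKY factors 8 rose and 24 fell (9 and 24 adjusted over the list alone), and of 57 NAC factors 2 rose and 19 fell (2 and 17 adjusted over the list alone), with -2.16 for Os07g0683200. Camera gave adjusted p-values of 2.91e-05 for cell wall, 0.000204 for auxin response and for class III peroxidases, 0.00657 for defence, 0.0305 for WRKY and 0.00601 for NAC. With an estimated correlation all had adjusted p = 0.332 except WRKY with adjusted p = 0.392. With median centring cell wall (adjusted p = 0.0959), class III peroxidases (0.126), defence (0.148), WRKY (0.172) and NAC (0.125) lost their calls, as did WRKY without 18-day replicate 2 (0.0955). Of 40 seed storage markers 4 rose and 15 fell (4 and 16 adjusted over the list alone) and of 35 root markers 5 rose and 14 fell, also when adjusted over the list alone. These lists had adjusted p = 0.0177 and 0.0305, and adjusted p = 0.332 and 0.396 with an estimated correlation. With median centring they had 0.155 and 0.148, the seed list with no filter on dim probes had 0.101, and the root list without 18-day replicate 2 had 0.0772.

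Of 32 splicing factors 15 rose and 0 fell by limma at 18 days (17 and 0 adjusted over the list alone, 19 and 0 at an unadjusted p under 0.05), with 5.64 for PRP18 Os03g0701100, and of 47 organelle ribosomal proteins 19 rose and 1 fell (21 and 2 adjusted over the list alone). Their adjusted p-values were 0.000218 and 6.21e-05, each with adjusted p = 0.332 with an estimated correlation, and with median centring 0.509 and 0.952. Of 53 core histone and replication genes 18 rose and 9 fell (23 and 9 adjusted over the list alone, list adjusted p = 0.0582), a direction that turned downward with median centring (adjusted p = 0.824). Of 46 cyclins and cell cycle kinases 3 rose and 17 fell (4 and 17 adjusted over the list alone, list adjusted p = 0.0852). Of 26 LEA and dehydrin genes 10 rose and 3 fell (10 and 5 adjusted over the list alone, list adjusted p = 0.281), with 3.44 for COR410 Os02g0669100. Of 86 ERF and DREB factors 28 rose and 18 fell (29 and 22 adjusted over the list alone, list adjusted p = 0.231), with 6.64 for Os02g0546600 and 4.97 for Os02g0764700. The 22 lists that did not pass had adjusted p-values from 0.0520 to 0.973. Among them, proteasome, aquaporins and chlorophyll breakdown with senescence had a median and a mean of opposite sign. Large single falls were those of the O-methyltransferase Os12g0441600 at -4.28, the disease resistance response proteins Os08g0375400 and Os07g0636600 at -3.98 (with -3.22 and -4.73 on the single arrays) and -3.62, the pepsin-family peptidase Os10g0537800 at -3.92, the peroxidase Os07g0677200 at -3.70 and Os02g0230300 at -4.65 (with -3.88 and -5.41 on the single arrays). The P450 Os03g0658800 changed by -4.00, but by -0.33 on another of its probes (adjusted p = 0.129, the highest over the alternatives). Os01g0860500 and Os06g0228200, at 4.27 and -1.84, turned sign on another probe, to -0.08 and 0.21.

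With an estimated correlation camera passed 0 of 37 lists at 24 days, 0 at 18 days and 0 in the difference between the ages, with 2, 2 and 2 lists at an unadjusted p under 0.05. Even the planted list of the simulation reached only an unadjusted camera p of 0.00521 this way, so these counts do not decide whether lists changed. The simulated genes were drawn independently, so the simulation does not secure the calls at the preset correlation for correlated genes either. At the preset correlation camera passed 18, 15 and 8, and fry passed 30, 27 and 8. Fry does not set a list against the other genes. With 53.9% of all genes called at 24 days, a list can pass in fry without changing more than the others. With median centring camera passed 18, 5 and 22, the 22 including upward differences of small heat shock proteins (adjusted p = 0.0353, from 0.00248 to 0.898 over 9 alternatives), HSP70 (0.00623, from 0.00623 to 0.613) and heat stress transcription factors (0.00802, from 0.00802 to 0.703). Lists that passed in fry but not in camera at 24 days included programmed cell death (down, adjusted p = 0.0199, from 0.0199 to 0.807 over 9 alternatives), DnaJ co-chaperones (up, 0.00586, from 0.00586 to 0.438), glutathione S-transferases (up, 0.00651, from 0.00651 to 0.329) and ZIM genes (down, 0.00586, from 0.00586 to 0.340). ER folding passed upward in fry (0.0359) and with median centring (0.0267) at 24 days, with a range of 0.0267 to 0.626, and defence proteins passed downward in fry (0.0212), without either 18-day array (0.0428) and without 24-day replicate 1 (0.0486), with a range of 0.0212 to 0.438. At 18 days histones passed upward in fry (0.0160) and with no filter on dim probes (0.0398), with a range of 0.0160 to 0.824.

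The response to heat shock differed between the ages by the largest amounts in single genes such as the nicotianamine synthase Os03g0307300, and the histone, cell cycle, cell wall and LEA lists passed the test of the difference at the preset correlation. All 4 list calls ended with an estimated correlation (adjusted p = 0.441), and that of the cell wall list also in fry (adjusted p = 0.0655). Of 3 tested nicotianamine synthases, which make the metal chelator nicotianamine, Os03g0307300 and Os03g0307200 rose by 7.10 and 6.61 at 24 days and fell by 1.07 and 1.19 at 18 days. Their differences were 8.17 (SE 0.18) and 7.80 (SE 0.17), both with a limma adjusted p = 0.00192 and n = 2 arrays per age. The third, Os07g0689600, changed by -0.30 at 24 days (limma adjusted p = 0.122, and called as a fall with a dye term and with no background correction, with a range of 0.0342 to 0.599 over the alternatives) and by -1.28 at 18 days, and the difference was not called (0.99, limma adjusted p = 0.0603). The CBF-like gene Os09g0522000, of a family of cold-response regulators, fell by 4.88 at 24 days and rose by 1.34 at 18 days, a difference of -6.22 (SE 0.30, limma adjusted p = 0.00556). Its 18-day call ended with median centring. Of 25664 genes, 1299 had a called difference, 359 higher and 940 lower at 24 days. Of these, 64 rose at 24 and fell at 18 days, 114 did the reverse, and 492 were called in one direction at both ages. The count was 483 with median centring, 541 and 544 without 24-day replicates 1 and 2, 4064 and 4607 without 18-day replicates 1 and 2, 3387 with no background correction and 3523 with a dye term. The share of higher calls was 27.6%, against 39.0% with the processed signals, 39.1% with the series matrix and 37.8% and 41.0% without 18-day replicates 1 and 2. Each age was hybridised on its own slide and scanned on its own, so slide and age cannot be told apart for the difference.

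**Figure D2:**
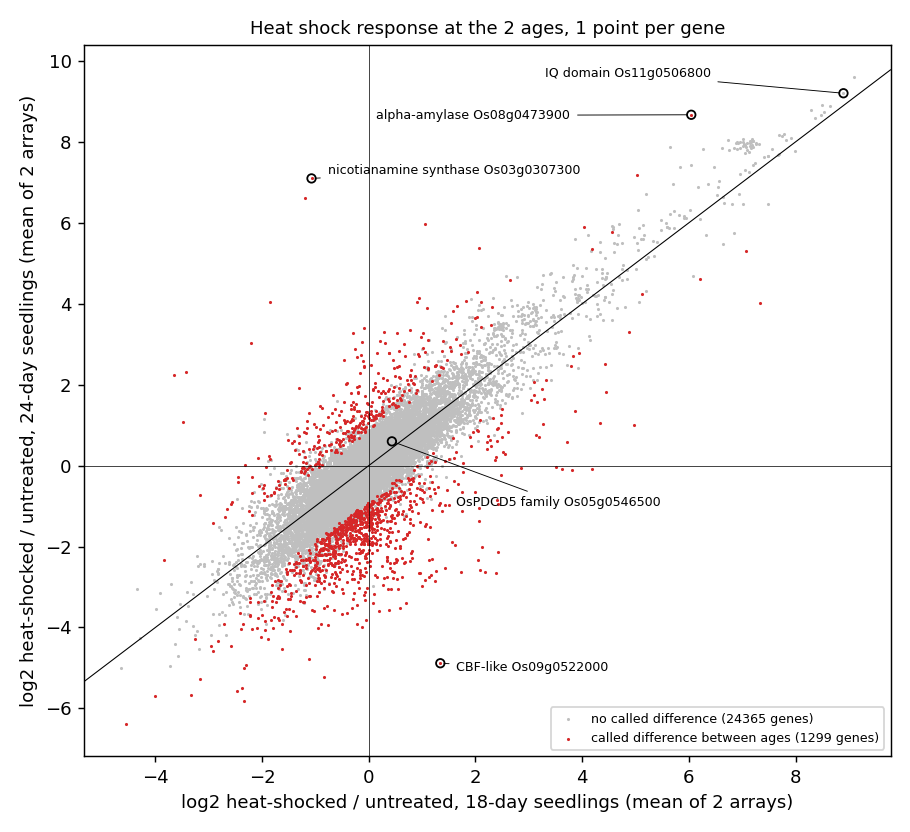
Log2 ratio of heat-shocked over untreated signal in 18-day (horizontal axis) and 24-day seedlings (vertical axis), each the mean of 2 arrays, with 1 point per gene, the line of equal change, and the 1299 genes with a called difference in red. The nicotianamine synthase Os03g0307300 lies far above the line and the CBF-like gene Os09g0522000 far below it.

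The histone list went in opposite directions at the ages, with a median of -0.47 at 24 days and of 0.33 at 18 days, where it did not pass (adjusted p = 0.0582) and turned downward with median centring (adjusted p = 0.824), as at 24 days. Of 53 histone and replication genes 16 had a lower and 0 a higher change at 24 days by limma (29 and 0 adjusted over the list alone, 30 and 1 at an unadjusted p under 0.05), with -1.42 (SE 0.16) for Os05g0113900, and their median difference was -0.71. Of 46 cyclins and cell cycle kinases 11 were lower and 0 higher (17 and 0 adjusted over the list alone, 22 and 0 at an unadjusted p under 0.05), with -1.97 for the kinesin Os03g0587200 and -1.56 for the cyclin Os06g0726800. Of 106 cell wall genes 16 were lower and 0 higher (31 and 1 adjusted over the list alone, 44 and 5 at an unadjusted p under 0.05), with -1.63, -1.69 and -1.39 for Os01g0823100, Os02g0658800 and Os07g0119400. Of 26 LEA and dehydrin genes 10 were higher and 0 lower (17 and 1 adjusted over the list alone, 17 and 2 at an unadjusted p under 0.05), with 2.87 for RAB 16B Os11g0454200 and 2.27 for Os06g0110200, and of 61 glutathione S-transferases 5 were higher and 0 lower (13 and 1 adjusted over the list alone, 18 and 5 at an unadjusted p under 0.05). Camera's adjusted p was 1.26e-10 for histones, 2.23e-07 for cyclins, 2.92e-05 for cell wall, 6.31e-09 for LEA and 0.00158 for glutathione S-transferases, and for all 5 adjusted p = 0.441 with an estimated correlation. The cell wall list also lost its call in fry (adjusted p = 0.0655). Of 40 seed storage markers 8 were lower and 2 higher (16 and 2 adjusted over the list alone), with adjusted p = 0.000588, adjusted p = 0.441 with an estimated correlation and 0.124 with no filter on dim probes. The 156 cytosolic ribosomal and 57 proteasome genes had 0 single differences by limma, also when adjusted over the lists alone, and 2 higher and 0 lower in each list at an unadjusted p under 0.05, while their lists passed upward (adjusted p = 0.0218 and 0.0242). These had adjusted p = 0.739 and 0.613 with an estimated correlation and 0.607 and 0.197 in fry. The cytosolic list lost its call without 24-day replicate 2 (0.329) and without 18-day replicate 1 (0.267), and the proteasome list without any 1 of the 4 arrays (0.0809 to 0.139).

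Single jasmonate genes differed between the ages, while most members of their lists and the lists themselves did not pass. The ZIM genes Os10g0391400 and Os03g0180800 differed by -4.14 (SE 0.29) and -2.83 (SE 0.23), and 3 of 13 ZIM genes were lower at 24 days, also when adjusted over the list alone, where 2 were higher (list adjusted p = 0.923). Of 35 ethylene and jasmonate synthesis genes 5 were higher and 3 lower (6 and 4 adjusted over the list alone, list adjusted p = 0.477), with 2.30 for Os06g0216300, 1.45 for the lipoxygenase Os02g0194700, -1.94 for lipoxygenase L-2 Os03g0738600 and -1.33 for Os03g0767000. Of 86 ERF and DREB factors 3 were higher and 19 lower (8 and 25 adjusted over the list alone, list adjusted p = 0.0749), with 1.95 for RAP2.6 Os12g0168100, -3.96 for Os02g0764700 and -4.81 for Os04g0610400. This list passed downward in 6 of 9 alternatives, namely fry (adjusted p = 0.0372), median centring (0.0251) and without any 1 of the 4 arrays (0.00231 to 0.0218), and its adjusted p ran from 0.00231 to 0.613 over all 9. Of 66 WRKY factors 1 was higher and 10 lower (5 and 16 adjusted over the list alone, list adjusted p = 0.567), with -3.68 and -2.98 for Os01g0821600 and Os08g0386200. The ribonucleases Os09g0537700 and Os09g0538000 differed by 5.90 and 5.24, the En/Spm-like gene Os07g0431000 by 5.74 and PR1a Os07g0124900 by 4.56, which depended on the array, with -2.58 and -4.39 on the single 18-day arrays, and on the probe (2.02 on another). The EF-hand protein CCD1 Os06g0683400 differed by -5.02, the kinase Os01g0699600 by -4.67, the U-box protein Os05g0476700 by -4.38 and the rhomboid-like Os10g0521900 by -4.37. Of 29 programmed cell death genes 0 had a called difference by limma, while 1 was higher and 4 lower adjusted over the list alone and 2 were higher and 7 lower at an unadjusted p under 0.05 (list adjusted p = 0.582). Bax inhibitor-1 Os02g0125300 differed by -1.11 (SE 0.23, limma adjusted p = 0.0705). The median and the mean or test differed in sign for ER folding, WRKY, NAC, ZIM, galactinol with raffinose and trehalose, and root markers. Of 47 named genes with a called difference, 31 were called in each of the 16 alternatives. The other 16 were the cell wall genes Os01g0823100, Os02g0658800 and Os07g0119400, the histone Os05g0113900, the cyclin Os06g0726800, RAP2.6 Os12g0168100, Os02g0194700 and Os03g0767000 of jasmonate synthesis, PR1a Os07g0124900, and Os03g0241900, Os03g0658800, Os03g0667300, Os04g0460600, Os04g0644400, Os04g0678700 and Os08g0473900.

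Untreated seedlings of the ages, compared by the separate-channel fit, differed widely in single genes. The nicotianamine synthases Os03g0307300 and Os03g0307200 were 286-fold and 197-fold lower in untreated 24-day than in untreated 18-day seedlings, at -8.16 (SE 0.11, limma adjusted p = 7.31e-07) and -7.62 (SE 0.17), while the third, Os07g0689600, was higher by 1.45 (limma adjusted p = 0.000242). Also lower were further single genes, with -5.09 for the Fe(II) transport protein Os03g0667300 (34.0-fold), -4.95 for Nramp6 Os07g0258400 (30.9-fold) and -5.85 for the bHLH gene Os01g0952800 (57.6-fold). Higher at 24 days were CI2C Os12g0548700 at 6.89 (SE 0.22, 118-fold), the Bowman-Birk inhibitor Os01g0127600 at 6.22 (SE 0.12, 74.4-fold), ZIM gene Os10g0391400 at 5.51 (45.7-fold) and lipoxygenase L-2 Os03g0738600 at 5.04 (33.0-fold). The kinase Os01g0699600 was 104-fold higher, and Os12g0198700, described as a beta-glucosidase aggregating factor, 31.3-fold higher, while the RNase S-like Os09g0538000 was 40.2-fold lower. Of 25664 genes 5609 differed, 3283 higher and 2326 lower at 24 days. Quantile normalization over all channels gave 6601, of which 3414 were higher and 3187 lower (51.7% higher). Among histone and replication genes 30 of 53 were higher and 0 lower by limma (34 and 1 at an unadjusted p under 0.05), among cyclins and cell cycle kinases 23 of 46 were higher and 2 lower, and among LEA and dehydrin genes 2 of 26 were higher and 16 lower. Of 16 meristem markers 7 were higher and 0 lower by limma (9 and 0 at an unadjusted p under 0.05). Of 40 seed storage markers 10 were higher and 4 lower, and of 35 root markers 9 were higher and 9 lower. Whether the share of these tissues differed was not tested. Without 24-day replicate 1 the count was 1400 with 70.2% higher, and without 24-day replicate 2 it was 1493 with 71.6% higher, against 58.5% in all arrays. The comparison ran across slides, so slide and age cannot be told apart here either.

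**Figure D3:**
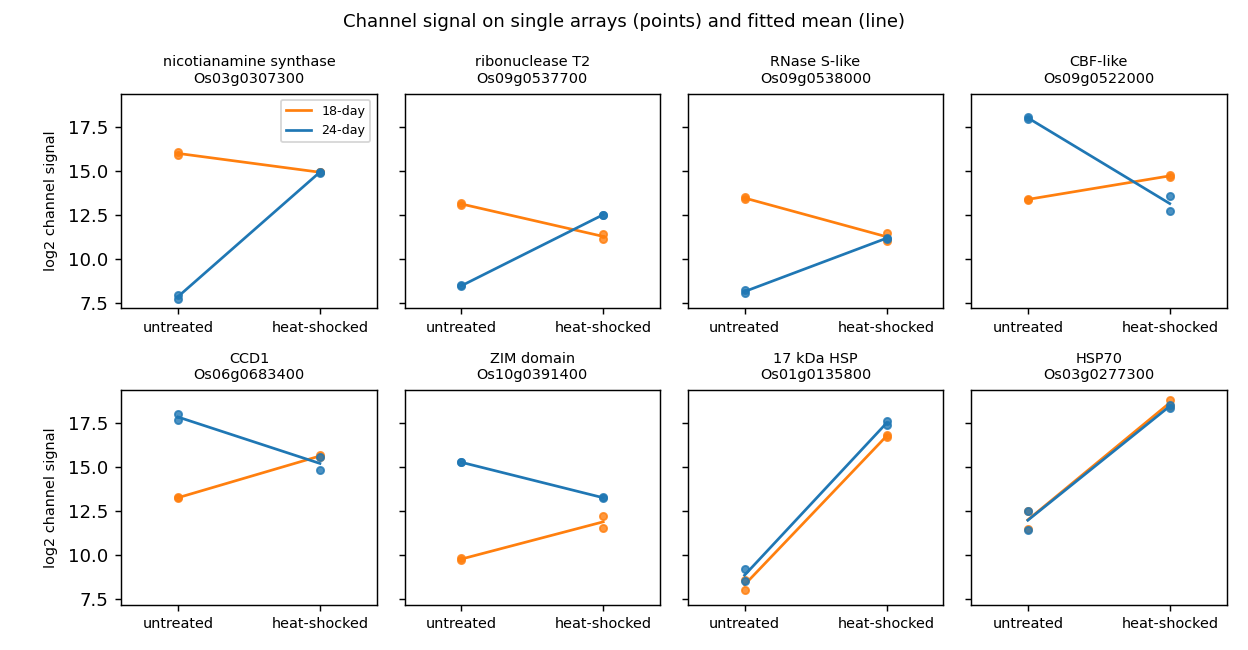
Log2 channel signal (vertical axis) of 8 genes in untreated and heat-shocked seedlings (horizontal axis) of 18 and 24 days, with single arrays as points and the fitted mean as a line. The nicotianamine synthase Os03g0307300 differs between the ages by -8.16 in untreated and by 0.01 in heat-shocked seedlings.

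Of the 1299 genes with a called difference in the heat shock response, the ages differed more in the untreated than in the heat-shocked seedlings for 866 (66.7%), against 44.7% of all genes. Their median absolute difference was 0.98 in untreated and 0.58 in heat-shocked seedlings. In heat-shocked seedlings 7046 genes differed between the ages, 3029 higher and 4017 lower at 24 days. The nicotianamine synthase Os03g0307300 differed by 0.01 (limma adjusted p = 0.950) and Bax inhibitor-1 Os02g0125300 by 0.03 (limma adjusted p = 0.906) in heat-shocked seedlings, while lipoxygenase L-2 Os03g0738600 still differed by 3.10 and CI2C Os12g0548700 by 4.99. The untreated difference of Bax inhibitor-1 was 1.14 (SE 0.15, limma adjusted p = 0.00251).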

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

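The tests of exchanged labels, of slide scale on the genes that moved in opposite directions and of normalization on the 18-day value of the OsPDCD5-family probe were chosen only after the results were seen.

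The response to heat shock differed between the ages, by the test of the difference itself, in 1299 genes and, at camera's preset correlation, in 8 gene lists. With an estimated correlation 0 of 37 lists passed in camera, with 2 at an unadjusted p under 0.05, and these 8 had adjusted p = 0.441 to 0.739, while with median centring 22 lists passed. An estimated correlation also weakened the planted list of the simulation, so it does not decide whether the lists differed. The simulated genes were independent, so calls at the preset correlation are not secured for correlated genes either. The lists' median log2 differences, 24 minus 18 days, were 0.11 for glutathione S-transferases, -0.71 for core histones and replication, -0.43 for cyclins and cell cycle kinases, 0.0876 for cytosolic ribosomal proteins, 0.12 for the proteasome, 1.03 for LEA and dehydrins, -0.42 for cell wall loosening and synthesis and -0.39 for seed storage markers. Of the 1299 genes, 66.7% differed more between the untreated than between the heat-shocked seedlings. An exchange of heat-shocked and untreated RNA in the labels of one age is argued against by the chaperone lists, where 0% of the 78 genes called at both ages went in opposite directions and 65 rose at both. Normalization within arrays stays open. For the 1299 genes, the median ratio of the differences under 4 other signal treatments to those reported was at its lowest 0.987, with median centring. The median size of these differences thus did not hang on the loess. The genes were, however, chosen by their reported differences, and each treatment either kept the loess or normalized within the array in another way. The ratio therefore cannot tell whether normalization had a part. Median centring also raised the median SE of the difference from 0.189 to 0.414 and left 483 calls. A different scale of the log ratios on the slides cannot turn a direction, and 13.7% of the genes with a called difference went in opposite directions at the ages. For the other 1121 genes it could have played a part, since 85.8% of them changed more at 24 days, a share between the bounds set for either reading, and for these slide scale and age cannot be told apart. Age stays open as an untested biological difference, as does a different state of the untreated seedlings on the day of harvest.

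The rise of the OsPDCD5-family probe Os05g0546500 was under 2-fold at both ages although induced expression was the study's subject. Compression of the ratios of bright probes stays open. Of 3106 genes within 1 log2 unit of its mean brightness over both channels, 3.96% were called and rose at least 4-fold at 24 days. Such genes can be dim when untreated. The largest rise among them was 8.17, the value of Os01g0136200, whose untreated log2 signals at 24 days were 9.05 and 12.30. Os05g0546500 was bright in both channels, with 14.59 and 14.64 untreated and 15.16 and 15.26 heat-shocked at 24 days. Normalization within arrays could account for the 18-day rise, which came to -0.0363 with median centring, where the residual SD between arrays grew from 0.188 to 0.342. The 24-day rise kept its size over the same treatments, with a lowest value of 0.56. With median centring it was 0.58, but its call ended (limma adjusted p = 0.152). Each of these treatments either kept the loess or normalized within the array in another way. They therefore cannot tell whether normalization had a part in the 24-day rise. A probe that reads the native gene and not the transgene stays open as an explanation, since its place in the construct is not known here.

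The following named genes also differed between the ages by the test of the difference, given as log2 difference, 24 minus 18 days. Higher at 24 days were Os03g0307300 (8.17), Os03g0307200 (7.80), Os09g0537700 (5.90), Os07g0431000 (5.74), Os09g0538000 (5.24), Os07g0124900 (4.56), Os11g0454200 (2.87), Os08g0473900 (2.62), Os07g0258400 (2.53), Os06g0216300 (2.30), Os06g0110200 (2.27), Os01g0952800 (2.26), Os12g0168100 (1.95), Os07g0638400 (1.87), Os02g0194700 (1.45) and Os03g0667300 (1.19). Lower by over 3 were Os09g0522000 (-6.22), Os06g0683400 (-5.02), Os04g0610400 (-4.81), Os01g0699600 (-4.67), Os05g0476700 (-4.38), Os10g0521900 (-4.37), Os10g0391400 (-4.14), Os02g0661100 (-4.11), Os02g0764700 (-3.96), Os12g0198700 (-3.79), Os01g0821600 (-3.68), Os02g0616100 (-3.47), Os01g0127600 (-3.20), Os02g0814200 (-3.13) and Os02g0308800 (-3.11). Lower by less were Os08g0386200 (-2.98), Os03g0180800 (-2.83), Os03g0339300 (-2.66), Os04g0644400 (-2.32), Os03g0587200 (-1.97), Os03g0738600 (-1.94), Os03g0658800 (-1.70), Os02g0658800 (-1.69), Os01g0823100 (-1.63), Os06g0726800 (-1.56), Os05g0113900 (-1.42), Os07g0119400 (-1.39), Os03g0241900 (-1.35), Os03g0767000 (-1.33), Os04g0678700 (-1.28) and Os04g0460600 (-1.22).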

How the results depend on the processing

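Counting identical probe sequences once and a replicate block were the alternatives chosen after the data were seen. Counting sequences once gave 13391 calls at 24 days, 9675 at 18 days and 1380 for the difference. At 24 days, with 13844 calls, median centring gave 7762, a change of at least 2-fold 5966, the arrays of an age as 1 replicate with no test 5151, and leaving out single arrays 7337 to 16774, the lowest counts coming without 24-day replicate 1 (7611) or 2 (7337). At 18 days, with 9998 calls, a dye term gave 15371, a change of at least 2-fold 4121, the arrays as 1 replicate 2930, and leaving out single arrays 8099 to 13471. For the difference, with 1299 calls, no background correction gave 3387, the processed signals 2846, the series matrix 2821, a dye term 3523, median centring 483, and leaving out single arrays 541 (without 24-day replicate 1), 544 (24-day replicate 2), 4064 (18-day replicate 1) and 4607 (18-day replicate 2). For the untreated seedlings, with 5609 calls, leaving out single arrays gave 1400 to 5840, with 1400 and 1493 without 24-day replicates 1 and 2. Where 1 array of an age is left out, the other is assumed to vary like the other age's pair and its dye effect does not cancel. Gene lists passed 41 times with the preset correlation, 0 times in camera with an estimated correlation (2, 2 and 2 lists at an unadjusted p under 0.05 at 24 days, 18 days and in the difference) and 65 times in fry. With median centring 18, 5 and 22 lists passed at 24 days, at 18 days and in the difference, against 18, 15 and 8. The stricter thresholds lower counts by construction, and for the other counts the cause was not tested. Median centring moved the median of all genes to -0.15 at 24 and -0.12 at 18 days. It turned the 18-day change of Os05g0546500 to -0.0363 and turned 3 lists that had not passed into calls of the opposite direction, the proteasome at 18 days (adjusted p = 0.0453, down) and, in the difference, photosystem and antenna proteins (0.0289, up, against down with a dye term at 0.00173, without 18-day replicate 2 at 0.000132 and without 24-day replicate 1 at 1.17e-05) and organelle ribosomal proteins (0.00478, up). Another probe turned the 18-day changes of Os01g0860500 to -0.0769 and of Os06g0228200 to 0.21, for which the cause was not tested. Of the named genes' values under the alternatives, 2010 at 24 days kept their side of the threshold, 19 lost and 8 gained a call. At 18 days these numbers were 1972, 33 and 29, with 3 called changes reversed (changes not called that turned sign count as kept), for the difference 737, 62 and 0, with 0 reversed, and for the untreated seedlings 84, 0 and 0. Of 47 named differences 31 were called in each of 16 alternatives, and the most losses came with median centring (13) and without 24-day replicate 1 (11) or 2 (11). The replicate numbers are shared by the ages but mark only the dye orientation, so a replicate block is the same fit as the dye term, with 1 residual degree of freedom, and gave 18182 calls at 24 days, 15371 at 18 days and 3523 for the difference. Signal over background limits the dim genes, and 82.4% to 87.0% of the spots were well above it.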

Other observations

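The families, transposable elements and clock genes described here, and their tests, were chosen only after the results were seen. Of 162 families of genes with one shared description tested with camera, those of G-D-S-L lipolytic enzymes, secreted lipases and esterases, had the lowest p at 24 days, with 3 of 75 rising and 49 falling (adjusted p = 5.24e-07, and adjusted p = 0.680 with an estimated correlation). At 18 days 4 rose and 44 fell (adjusted p = 3.27e-06, and adjusted p = 0.735 with an estimated correlation). Of 461 genes described as protein kinase domain proteins, 48 rose and 250 fell at 24 days (adjusted p = 1.70e-06, and 0.680 with an estimated correlation) and 35 rose and 158 fell at 18 days (adjusted p = 7.43e-05, and 0.735 with an estimated correlation). Of 43 Harpin-induced 1 domain genes 2 rose and 34 fell at 24 days (adjusted p = 1.70e-06, and 0.680 with an estimated correlation). Of 17 fasciclin-domain genes, whose products are cell surface proteins, 15 fell at 24 days (adjusted p = 4.18e-05, and 0.680 with an estimated correlation).

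Several retroelement genes were among the large rises at both ages. Os08g0133100, described as a retroelement pol polyprotein, rose by 8.19 at 24 and 7.79 at 18 days, and the reverse transcriptase genes Os03g0561400 and Os01g0554100 rose by 7.65 (8.24 and 7.06 on the single arrays) and 4.15 at 24 days and by 7.48 and 3.89 at 18 days. Of 111 genes with a transposable element in their description 44 rose and 16 fell at 24 days (adjusted p = 0.00953, and adjusted p = 0.796 with an estimated correlation), and at 18 days 24 rose and 10 fell and the list did not pass (adjusted p = 0.0878). A single probe sequence stood under 34 gene identifiers and made up 31 of the 60 largest rises at 24 days, with a median log2 change of 7.93 at 24 and 7.04 at 18 days. In all, 202 probe sequences stood under more than 1 identifier and covered 946 of the 25664 features. These were not merged in the counts and tests of lists, families and transposable elements, so features of one sequence count there as separate genes. How many of the 111 genes this concerns was not counted.

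Of 10 genes tested whose description names the clock or a response regulator, 6 were called at both ages, 5 of them higher and 1 lower. The Gigantea homologue Os01g0182600 rose by 2.91 at 24 and 3.36 at 18 days, and the response regulator receiver genes Os02g0618200 and Os09g0532400 rose by 3.91 and 2.88 at 24 and by 4.80 and 3.00 at 18 days. The clock coupling factor ZGT, Os01g0802600, rose by 3.87 and 2.14, the latter with 1.30 and 2.98 on the single arrays. A hypothesis is that heat-shocked and untreated seedlings may have been harvested at different hours of the day, 6 h of treatment apart. Of the genes called at both ages 0 went in opposite directions, and by limma 0 of these 6 had a called difference between the ages, with 2 at an unadjusted p under 0.05, which a direct effect of heat on these genes would give as well, so the hour of harvest and heat cannot be told apart without the harvest times.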
